A study of Homo sapiens with 48 samples.

How the data were processed

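RNA was measured by sequencing in 48 libraries, which the labels place in 16 groups of 3: U2OS cells with mouse STING1-350 in DMSO or DMXAA at 8 h, BJ-5ta WT and STING knockout cells in buffer or cGAMP at 6 h and 12 h, and a second set of BJ-5ta WT, C51 and C64 cells in buffer or cGAMP at 12 h. The first BJ set was made with the Illumina Stranded mRNA kit and the second with NEBNext Ultra II, per the labels, so kit and set are one split. Per the submitters' processing notes the authors trimmed reads with Trim Galore and quantified them with Salmon on hg38; versions and the transcript set are not stated. The deposited table of each library holds estimated reads, which are Salmon's expected counts, for each RefSeq transcript. It also holds TPM, transcripts per 1e6 transcripts, and effective length in bases, per the file headers. The authors also deposited gene tables in TPM, which were used only to check the sums made here. Of the genes named in both, 98.23% or more in each library were within 0.1% of the deposited value, with a small absolute allowance in TPM. Genes at 0 in both counted as equal, and genes missing from either were left out. Mouse STING is not among the transcripts, so its level was not measured.

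Expected counts were summed over the transcripts of each gene of GRCh38.p14 and rounded. Of 76267 transcripts in the first file set 75799 matched the RefSeq table, 194 matched through the GENCODE metadata and 274 did not match, which gave 28005 genes; in the second set 70013, 292 and 324 of 70629 gave 27931 genes. Unmatched transcripts held at most 0.041% of a library's reads. Total estimated reads had a median of 25.0 M (M, 1e6) in U2OS, 34.65 M in the first BJ set and 45.2 M in the second. A gene with no read in a group can still have up to 3 counts over that group, and folds against such a group are given as lower bounds against that floor. Intervals and floors cover counting error only. Genes that share reads with paralogs or readthrough transcripts are uncertain, because Salmon divides such reads by a model.

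Genes were tested in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr, and the quasi-likelihood test with one coefficient per group, fitted apart for U2OS (6 libraries), the first BJ set (24) and the second (18). These fits kept 14732, 14924 and 15062 genes. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a false discovery rate of 0.05, and a prior count of 2 was used for log2 CPM. A gene is said to rise or fall only when it passed. The comparisons were treatment against its control in each line and time, differences between such responses (WT minus STING knockout, 12 h minus 6 h, and C51, C64 or their mean minus WT) and knockout against WT in buffer. Replicate numbers showed no pairing between groups, so libraries were not paired.

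The 26 gene lists were written from general knowledge before the data were examined: interferon-stimulated genes (42 genes), interferons and interferon-linked chemokines (14), NF-kB targets (33), lysosomal hydrolases and cofactors (48), lysosomal membrane proteins (29), V-ATPase subunits (20), autophagy genes (40), RAG and folliculin nutrient signalling (24), unfolded protein and integrated stress response (28), cholesterol synthesis (25), S phase and replication (24), mitosis (24), p53 targets (22), fibroblast extracellular matrix (27), immediate early genes (22), heat shock (16), NRF2 targets (20), hypoxia and glycolysis (22), class I antigen presentation (20), cytosolic DNA sensing (19), nuclear genes of the respiratory chain (24), cytosolic ribosomal proteins (26), and markers of blood (12), epithelial (13), endothelial (11) and neural (12) cells. Lists with 5 or more tested members were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the residuals. Beside the lists, named genes followed a rule fixed at the same time. It took STING1, TFEB and TFE3, a panel of 33 genes, and the 6 highest and 6 lowest genes of each comparison. Those extremes had to pass, have an average log2 CPM of 1 or more and not overlap between groups. For differences between responses the overlap was checked in a WT arm only. Each called list gave the 4 members with the lowest adjusted p among those that passed and moved in the list's direction. The text names part of these.

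The alternatives chosen before the data were examined were DESeq2 1.42.0 size factors, DESeq2's Wald test, limma-voom, no filter on low counts, counts from length-scaled TPM, a block for the replicate number, a fit of only the groups compared, and every fit with 1 library left out. Added after the data were seen were fits without 14 ribosomal RNA genes, U2OS libraries thinned to the smallest total, contrasts of C51 and of C64 with WT in buffer and in cGAMP, the C64 response minus that of C51, and the WT response of the second set minus that of the first. The method was tested on simulated data with 200 genes changed, built on 6 of the comparisons. A smaller further list was raised by less than 1.5-fold to test camera. Calls of its genes entered the total of calls and counted as neither recovered nor false. Of genes changed 1.5-fold, 55.2% to 80.6% were recovered, and of those changed 4-fold, 87.9% to 100%. The pass marks of this self-test were loosened after the first run missed them: recovery of 80% at 4-fold is now asked, and recovery need not rise with the fold. False calls were 11.4% in U2OS, 8.2% in C51 minus WT, 5.6% in WT minus knockout at 6 h, 4.9% in the second set's WT, 3.8% in WT at 6 h and 3% in the knockout at 12 h. These shares hold for the simulated number of changed genes and do not carry over to real comparisons that called many more genes.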

Results

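The series measured RNA by sequencing in 48 libraries of human cell lines given a compound that binds STING, or its control. STING is the membrane protein that binds the second messenger cGAMP and activates the kinase TBK1, which switches on the transcription factor IRF3 and the type I interferon genes. The first experiment used U2OS osteosarcoma cells stably expressing mouse STING1-350, a shortened protein which, per the labels, cannot activate TBK1. 3 libraries came from cells given 70 µM DMXAA, an agonist of mouse STING, for 8 h, and 3 from cells given DMSO. The second experiment used BJ-5ta cells, human foreskin fibroblasts immortalised with telomerase, either wild type (WT) or with STING1 knocked out. They received digitonin buffer with or without 1 µM cGAMP and were collected at 6 h and 12 h, which gave 8 groups of 3. A second set of BJ-5ta libraries, with another kit, compared WT cells with C51 and C64, a pair of lines in which the lysosomal transcription factors TFEB and TFE3 were both knocked out, in buffer and in cGAMP at 12 h, which gave 6 groups of 3. Estimated reads per library, in units of 1e6 (M), ranged from 11.0 to 26.5 M in U2OS, from 17.6 to 43.0 M in the first BJ set and from 39.7 to 55.1 M in the second. Changes below are log2 fold changes ± SE between groups of 3 libraries. The SE is the absolute change divided by the square root of the quasi-likelihood F, with a dispersion estimated over all libraries of a fit. For large folds from a group with few reads this SE can be too small, below counting error. Levels are counts per 1e6 reads (CPM) ± SD with n = 3. Adjusted p-values are from the edgeR quasi-likelihood test for genes and from camera for gene lists. Counts of list members are over all genes tested, with the count adjusted over the list alone beside them where it differed. The sample titles number the libraries of a group with the word brep, which they do not spell out. The labels do not state whether replicates were separate cultures, so every p-value measures only the spread between these libraries.

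The U2OS comparison set DMXAA against DMSO in cells whose mouse STING, per the labels, cannot activate TBK1. No U2OS cells without mouse STING, or with its full-length form, were measured. An effect of STING therefore cannot be told apart from other effects of DMXAA, and the role of TBK1 was not tested. Of 27 measured NF-kB targets, 23 rose and 1 fell (23 and 2 adjusted over the list alone), with a median log2 change of 1.94. TNFAIP3, which feeds back to restrain NF-kB, rose from 8.55 ± 0.33 to 272 ± 3.66 CPM (log2 4.99 ± 0.04, adjusted p = 2.03e-24), and the chemokine gene CXCL8 rose by 4.03 ± 0.14. All 20 immediate early genes rose (median 2.50), among them the nuclear receptor gene NR4A2 (5.04 ± 0.08) and MYC (2.89 ± 0.03). Interferon-stimulated genes went the other way: 24 of 31 fell and 2 rose (median -1.11), and the antiviral gene IFIT1 dropped from 11.1 ± 0.49 to 0.0821 ± 0.073 CPM. PARP9, DTX3L and SAMD9L, also induced by interferon, fell by 2.25 ± 0.08, 1.11 ± 0.05 and 3.98 ± 0.21, while ISG15 changed by -0.07 ± 0.16 (adjusted p = 0.682). IFNB1 had no read in the U2OS libraries, which allows up to 3 counts over each group, and the human STING1 gene stood at 3.09 ± 0.46 CPM in DMSO and 3.95 ± 0.53 in DMXAA (adjusted p = 0.0591; 0.0413 without DMSO replicate 1 and 0.0351 without DMXAA replicate 3). In camera the NF-kB (adjusted p = 3.7e-06), immediate early (5e-08) and interferon-stimulated (0.00076) lists differed from other genes with the preset correlation. None of these calls held when the correlation was estimated from 6 libraries: adjusted p = 0.13 with an estimated correlation for each of the 3 lists.

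Genes of lysosomes and autophagy rose in the same U2OS cells. Among 45 lysosomal hydrolases and cofactors 32 rose and 4 fell (31 and 4 adjusted over the list alone; median 0.38), with CTSB, the protease cathepsin B, up by 2.00 ± 0.03 and the sialidase gene NEU1 by 1.62 ± 0.03. Of 18 subunits of the V-ATPase, the proton pump that acidifies lysosomes, 15 rose and 2 fell (median 0.57). Of 38 autophagy genes 27 rose and 7 fell (median 0.61), and the receptor gene SQSTM1 went from 238 ± 1.27 to 1076 ± 13.2 CPM (log2 2.18 ± 0.02, adjusted p = 3.36e-23). Genes of the RAG GTPase and folliculin branch, which relays nutrient state at the lysosome to mTORC1 and TFEB, included FLCN (2.56 ± 0.04), FNIP2 (1.75 ± 0.06), RRAGC (1.75 ± 0.04) and RRAGD (1.69 ± 0.05). That list of 24 had 14 higher and 6 lower members and did not pass (adjusted p = 0.08). TFEB and TFE3 themselves rose by 2.15 ± 0.07 and 0.99 ± 0.03. The calls of the hydrolases (adjusted p = 0.001), the V-ATPase (0.00076) and autophagy genes (0.00072) were lost with the correlation estimated: adjusted p = 0.35, 0.16 and 0.24 with an estimated correlation. The 29 lysosomal membrane proteins, 17 higher and 9 lower, were not called (adjusted p = 0.12).

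Growth genes also moved in U2OS. Of 24 mitosis genes 23 fell and none rose (median -0.80), led by the kinesin gene KIF20A (-2.41 ± 0.04) and the kinase gene AURKA (-2.10 ± 0.04). Of 24 cholesterol synthesis genes 20 fell and 3 rose (median -0.50), including MVK, which encodes mevalonate kinase (-2.23 ± 0.09). All 26 cytosolic ribosomal protein genes rose (median 0.83), and 16 of 22 hypoxia and glycolysis genes rose while 3 fell (median 0.54), with the glucose transporter gene SLC2A3 up by 3.92 ± 0.03. Adjusted p-values were 3.2e-07, 0.002, 1.3e-08 and 0.00085 for these 4 lists, and adjusted p = 0.17, 0.35, 0.28 and 0.24 with an estimated correlation. The 24 S phase and replication genes had a median near 0, at -0.09. The largest rises outside the lists included SGK1, a kinase gene induced by stress and hormones (13.9 ± 0.24 to 692 ± 34.2 CPM), and the chemokine gene CCL3 (0.146 ± 0.086 to 17.6 ± 1.93 CPM). Genes that passed the test numbered 12114 of 14732, with 5802 higher and 6312 lower. The DMXAA libraries held 11.0 to 24.4 M reads against 25.6 to 26.5 M in DMSO. In simulated data of this design, with 200 genes and a smaller further list changed, 11.4% of 229 calls were false, above the nominal 5%. Far more genes were called in the real data, so this share does not carry over to the 12114 genes.

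In BJ WT cells cGAMP was compared with buffer to see the response of STING that can reach TBK1, first at 6 h. All 42 interferon-stimulated genes rose, with a median of 4.70. HERC5, which attaches ISG15 to proteins, went from 1.52 ± 0.12 to 1077 ± 51 CPM (log2 9.45 ± 0.09, adjusted p = 8.19e-28), IFIT1 rose by 8.66 ± 0.22 and ISG15 by 6.94 ± 0.15. IFNB1, the interferon beta gene, had no read in the buffer libraries and 10.6 ± 2.03 CPM after cGAMP, at least 286-fold higher against a floor of 3 counts over the group. CXCL10 was at least 614-fold higher in the same way. Of 11 interferon and interferon-linked chemokine genes 10 rose and 1 fell (median 8.73, or 7.64 with the genes at 0 counts set to their bound), and CCL5 rose by 8.65 ± 0.20. All 20 class I antigen presentation genes rose (median 1.43), with TAP1, a subunit of the peptide transporter, up by 3.81 ± 0.07. Adjusted p was 1.1e-31, 1.3e-06 and 4.4e-14 for these lists, and 0.0012, 0.0012 and 0.0027 with an estimated correlation.

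The lysosomal lists rose at 6 h too, by smaller amounts. Of 48 hydrolases and cofactors 44 rose and none fell (median 0.36), with LGMN, the protease legumain, up by 1.85 ± 0.04. Of 29 membrane proteins 21 rose (22 adjusted over the list alone; median 0.38) and of 19 V-ATPase subunits 15 rose (median 0.38). Autophagy genes had 20 of 39 higher and 7 lower (median 0.19), with GABARAPL1, an ATG8-family gene, up by 1.70 ± 0.06 and the receptor gene OPTN by 1.58 ± 0.05. FLCN, FNIP2 and RRAGC rose by 1.29 ± 0.06, 1.29 ± 0.09 and 1.46 ± 0.07. Of 28 genes of the unfolded protein and integrated stress responses 23 rose and 2 fell (24 and 2 adjusted over the list alone; median 0.62), and XBP1, a transcription factor of the endoplasmic reticulum stress response, went from 97.5 ± 4.95 to 994 ± 39.1 CPM. Adjusted p with an estimated correlation was 0.048 for membrane proteins, 0.0061 for the V-ATPase, 0.048 for autophagy and 0.0087 for the stress genes; the hydrolases (adjusted p = 7e-09) did not keep their call, with adjusted p = 0.083 with an estimated correlation.

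Other groups changed in WT cells at 6 h. NF-kB targets split, 15 of 32 higher and 11 lower (median -0.06, while the test pointed up; adjusted p = 0.36; the median was between -0.17, without cGAMP replicate 1, and 0.13 with 1 library left out): the cytokine gene IL6 rose from 24.3 ± 1.34 to 658 ± 12.9 CPM, and CXCL8 fell from 234 ± 65.4 to 24.2 ± 9.22 CPM. Of 24 mitosis genes 21 fell and 1 rose (median -0.63, adjusted p = 6.3e-05, and adjusted p = 0.32 with an estimated correlation). The p53 targets ZMAT3 and BTG2 fell by 1.99 ± 0.07 and 2.94 ± 0.14, with 15 of 22 in that list lower and 5 higher (adjusted p = 0.041, and adjusted p = 0.32 with an estimated correlation). Of 18 genes of cytosolic DNA sensing 10 rose and 3 fell (12 and 3 adjusted over the list alone; median 0.25, adjusted p = 0.0025, and 0.016 with an estimated correlation), among them STING1 itself (83.8 ± 3.32 to 222 ± 4.55 CPM). Of 23 nuclear genes of the mitochondrial respiratory chain 17 rose and 1 fell (median 0.22, adjusted p = 0.003, and adjusted p = 0.21 with an estimated correlation). Fibroblast extracellular matrix genes rose in 20 of 27 with 2 lower (median 0.32, adjusted p = 0.0024, and adjusted p = 0.11 with an estimated correlation). Among the lowest values were the calcium channel gene TRPC6 (-4.53 ± 0.19) and the cytoskeletal gene SHROOM3 (-4.43 ± 0.13). In all, 9831 of 14924 genes passed, 4880 higher and 4951 lower. WT cGAMP replicate 3 at 6 h stood apart, with 15.9% of its reads on 14 ribosomal RNA genes against 0.49% and 0.59% in the other 2 libraries of its group.

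The same comparison at 12 h asked how the response continued. All 42 interferon-stimulated genes rose again (median 5.92, adjusted p = 1.2e-26, and 0.0059 with an estimated correlation), while IFNB1 stood at 1.48 ± 0.15 CPM, at least 54.2-fold above buffer libraries with no read. Of 11 interferon and chemokine genes 8 rose (median 5.03, or 3.39 with bounds, adjusted p = 0.0026, and 0.027 with an estimated correlation). Of 48 hydrolases and cofactors 41 rose and 1 fell (median 0.51, adjusted p = 1.1e-07, and adjusted p = 0.11 with an estimated correlation), including CTSS, the protease cathepsin S (4.97 ± 0.14). GABARAPL1 went from 71.1 ± 8.24 to 693 ± 23.5 CPM and GPNMB, a lysosomal glycoprotein gene, rose by 2.00 ± 0.05. Genes of DNA replication and S phase fell, 23 of 24 with 1 higher (median -1.33, adjusted p = 2.3e-10, and adjusted p = 0.11 with an estimated correlation), such as the helicase gene MCM6 (-2.57 ± 0.06) and CCNE2, or cyclin E2 (-4.25 ± 0.13). Mitosis genes rose, 22 of 24 with 2 lower (median 0.97, adjusted p = 9e-06, and adjusted p = 0.26 with an estimated correlation), such as the checkpoint kinase gene TTK (2.16 ± 0.08) and CDK1 (1.65 ± 0.07). CXCL8 changed by 0.18 ± 0.33 (adjusted p = 0.629). The total was 10943 of 14924 genes, 5605 higher and 5338 lower, and it was 9586 by limma-voom.

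The difference between the 12 h and 6 h responses was tested itself and passed for 8418 genes, 4516 with a higher response at 12 h and 3902 with a lower. Such a difference can come from the buffer libraries as well as from the cGAMP libraries. From 6 h to 12 h the mean log2 CPM of p53 targets went from 5.55 to 5.07 in buffer. In cGAMP it went from 5.27 to 5.53. For NF-kB targets it went from 4.31 to 2.81 in buffer and from 4.26 to 3.66 in cGAMP. For mitosis genes it went from 6.52 to 6.06 in buffer and from 5.95 to 7.03 in cGAMP. The mitosis list had a higher response in 22 of 24 members (23 adjusted over the list alone) and a lower one in none (median 1.63, adjusted p = 1.4e-12, and adjusted p = 0.17 with an estimated correlation), with AURKA at 2.78 ± 0.13. For S phase 23 of 24 were lower and 1 higher (median -1.46, adjusted p = 1e-14, and adjusted p = 0.13 with an estimated correlation). The p53 targets were higher in 17 of 22 and lower in 1 (17 and 2 adjusted over the list alone; median 0.67, adjusted p = 0.00015, and adjusted p = 0.13 with an estimated correlation), and the chemokine gene CXCL1 was higher by 4.04 ± 0.28. Among interferon-stimulated genes 33 of 42 had a higher and 5 a lower response at 12 h (median 0.82, adjusted p = 5.3e-05, and adjusted p = 0.28 with an estimated correlation), IFIT1 being lower by -1.71 ± 0.23. Ribosomal protein genes were lower in 23 of 26 (24 adjusted over the list alone; median -0.36, adjusted p = 1e-05, and adjusted p = 0.56 with an estimated correlation).

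STING knockout cells tested whether the cGAMP response needs STING. ISG15 was 13.7 ± 0.2 CPM in buffer and 12.6 ± 1.51 in cGAMP at 6 h (log2 -0.13 ± 0.14), and IL6 changed by -0.17 ± 0.05 (adjusted p = 0.819). SQSTM1 and GABARAPL1 changed by 0.19 ± 0.06 and 0.27 ± 0.06 at 12 h, with adjusted p = 0.543 and 0.279, and DESeq2's Wald test gave 0.0488 for GABARAPL1. No gene passed at 6 h or 12 h by edgeR (0 of 14924), where 867 and 887 genes had an unadjusted p under 0.05, near 5% of the genes tested. DESeq2's Wald test gave 1 gene at 6 h and 17 at 12 h, limma-voom gave 0 at both, and an edgeR fit of only the 6 libraries compared gave 0 and 23. Several lists moved by small amounts with the preset correlation: interferon-stimulated genes at 6 h (median -0.11, adjusted p = 7.5e-07, and adjusted p = 0.39 with an estimated correlation) and S phase genes at 12 h (median -0.13; 0 members over all genes and 6 lower adjusted over the list alone; adjusted p = 2.5e-13, and adjusted p = 0.13 with an estimated correlation). At 12 h the interferon-stimulated list had a median of 0.08 and a mean of -0.03 (adjusted p = 0.00085 upward, and adjusted p = 0.37 with an estimated correlation). Leaving out 1 library at a time moved the first of these medians between -0.17, without cGAMP replicate 1, and -0.06, and the last between 0.04, without cGAMP replicate 2, and 0.10. In simulated data built on the 12 h comparison, 100% of genes changed 4-fold were recovered. The share was 73.1% at 2-fold and 80.6% at 1.5-fold. Many genes were changed there, which makes the adjusted threshold easier to pass. These shares therefore do not carry over to a comparison with few or no changed genes.

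The WT and knockout responses differed by direct test in 8252 genes at 6 h and 9283 at 12 h. All 42 interferon-stimulated genes responded more in WT at both times, with median differences of 4.79 (adjusted p = 6.7e-38, and 0.00046 with an estimated correlation) and 5.99 (1.9e-32, and 0.0021). IL6 differed by 4.94 ± 0.08 and 5.13 ± 0.13. The hydrolases responded more in WT in 41 of 48 genes at 6 h (43 adjusted over the list alone) and in 38 at 12 h with 1 lower, with median differences of 0.40 and 0.47; both calls were lost, with adjusted p = 0.08 and 0.12 with an estimated correlation. The difference for the V-ATPase list at 6 h (13 of 19 higher, median 0.41, adjusted p = 0.00035, and 0.0081 with an estimated correlation) and for class I antigen presentation (20 of 20 at both times; adjusted p = 0.0013 and 0.0027 with an estimated correlation) held. NRF2 targets, genes of the oxidative stress response, responded less in WT in 11 of 20 members and more in 2 at 12 h (median -0.38, adjusted p = 0.041, and adjusted p = 0.2 with an estimated correlation).

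Before cGAMP, the knockout and WT lines were compared in buffer. STING1 (NCBI gene 340061, chromosome 5, 139475533 to 139482758, GRCh38.p14) was at 35.6 ± 0.88 CPM in knockout and 83.8 ± 3.32 in WT cells at 6 h, and at 29.8 ± 0.91 and 87.5 ± 5.56 at 12 h, so its transcript remained detectable. NF-kB targets were higher in knockout cells at 6 h, 21 of 32 with 2 lower (median 0.79, adjusted p = 5.6e-11, and 0.045 with an estimated correlation): IL6 was at 99.2 ± 1.88 against 24.3 ± 1.34 CPM, and TNFAIP3 was higher by 1.45 ± 0.11. At 12 h IL6 was at 2.12 ± 0.21 against 2.34 ± 0.25 CPM (adjusted p = 0.385) and the list was not called (6 higher, 6 lower; adjusted p = 0.44). AJAP1, a junction protein gene, had no read in knockout buffer libraries and 54.7 ± 2.23 CPM in WT at 6 h, at least 2200-fold lower, and TGFBI, a matrix protein gene, was at 75 ± 2.88 against 324 ± 11.3 CPM at 12 h. GABARAPL1 was lower by -1.13 ± 0.06 and -1.55 ± 0.06. All 24 mitosis genes were higher in knockout cells at 12 h (median 0.61, adjusted p = 9.4e-15, and adjusted p = 0.12 with an estimated correlation). Totals were 4455 genes at 6 h (2185 higher, 2270 lower) and 5242 at 12 h (2564 higher, 2678 lower), so the lines differed before treatment. There is 1 knockout line, and its differences cannot be told apart from those between cell lines grown separately.

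**Figure D1:**
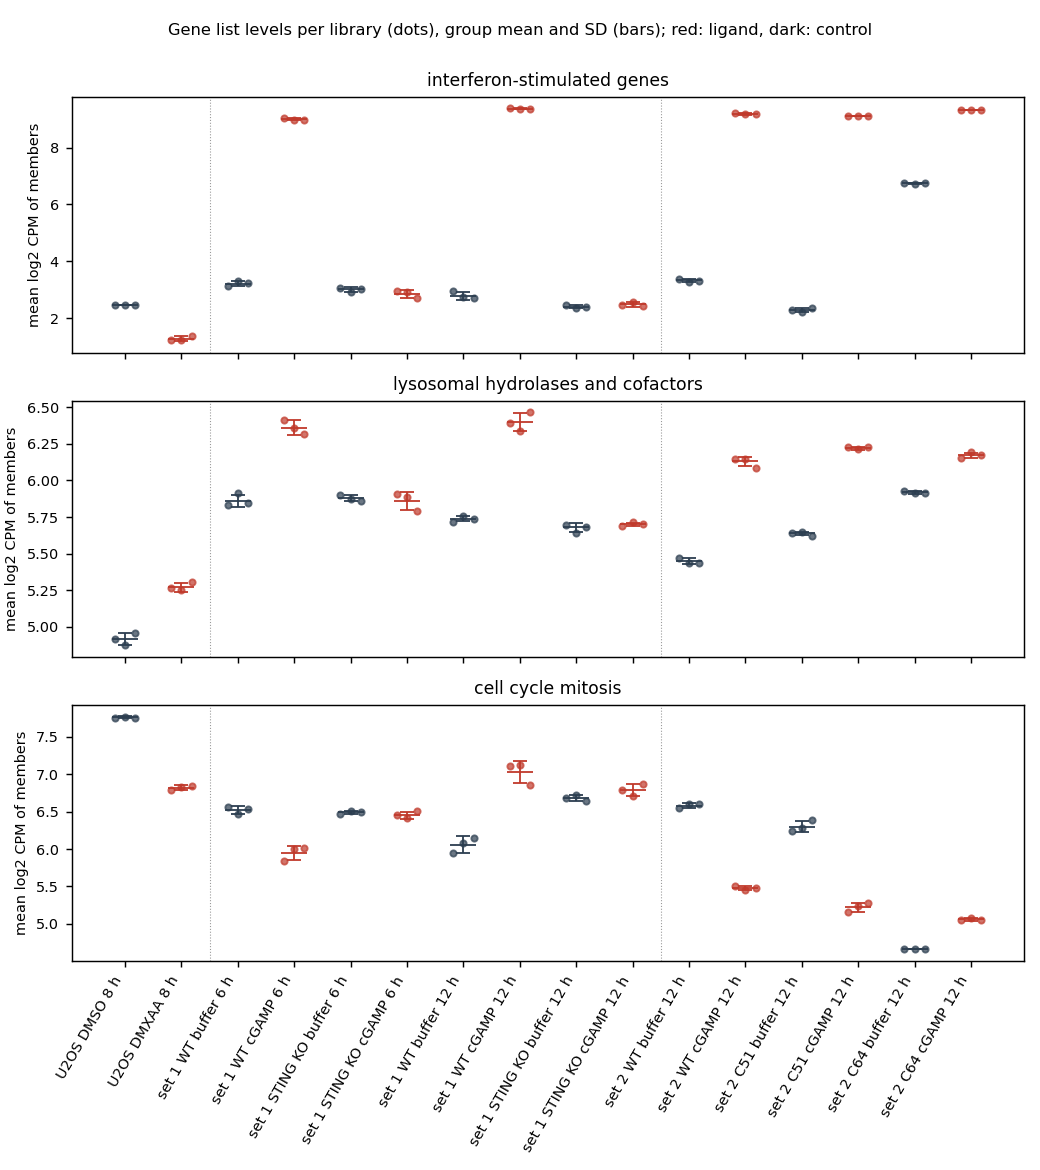
Mean log2 CPM of the members of 3 gene lists in each of the 48 libraries (dots), with the group mean and SD (bars); red marks DMXAA or cGAMP and dark blue marks DMSO or buffer, and dotted lines part the experiments. Interferon-stimulated genes averaged 2.79 in WT buffer and 9.37 in WT cGAMP at 12 h in the first set, 2.41 and 2.49 in STING knockout cells, 6.74 in C64 buffer, and 2.47 and 1.28 in U2OS DMSO and DMXAA.

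The second set repeated the 12 h comparison in WT cells, as the reference for the TFEB and TFE3 knockouts. All 42 interferon-stimulated genes rose (median 5.47, adjusted p = 9.1e-28, and 1e-04 with an estimated correlation), with IFIT1 going from 19.2 ± 1.39 to 4169 ± 147 CPM. Of 10 interferon and chemokine genes 9 rose (median 8.68, or 5.81 with bounds, adjusted p = 2.7e-05, and 0.0058 with an estimated correlation); IFNB1 was at least 37.6-fold higher. Hydrolases rose in 42 of 48 with 2 lower (median 0.50, adjusted p = 1.4e-10, and 0.0081 with an estimated correlation) and membrane proteins in 24 of 29 with 2 lower (median 0.52, adjusted p = 3.8e-06, and 0.0048 with an estimated correlation), such as CD68 (2.32 ± 0.04). SQSTM1 rose from 400 ± 21.7 to 751 ± 9.94 CPM and FNIP2 by 1.31 ± 0.07. S phase genes fell in 24 of 24 (median -1.07, adjusted p = 3.1e-10, and 0.012 with an estimated correlation). Mitosis genes fell in 23 of 24 (median -1.20, adjusted p = 3.4e-11, and adjusted p = 0.053 with an estimated correlation), the reverse of the first set at 12 h. Genes that passed numbered 10681 of 15062, 5548 higher and 5133 lower.

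The knockout lines were first compared with their own buffer libraries. In C51, 11184 genes passed (5544 higher, 5640 lower) and all 42 interferon-stimulated genes rose (median 6.30, adjusted p = 9.5e-28, and 1e-04 with an estimated correlation). IFNB1 was at least 50-fold higher in C51, at 1.09 ± 0.48 CPM, and in C64 it went from 0.0353 ± 0.026 to 1.78 ± 0.13 CPM. In C64, 10786 genes passed (5483 higher, 5303 lower), and the same 42 interferon-stimulated genes rose by a median of 2.23 (adjusted p = 7.5e-20, and 0.00056 with an estimated correlation) from a higher start: IFIT1 was at 398 ± 13.1 CPM in C64 buffer and 3669 ± 58.5 in cGAMP. NF-kB targets rose in 29 of 30 in C64 (median 1.62, adjusted p = 7.6e-10, and 0.012 with an estimated correlation), with CXCL8 going from 344 ± 5.99 to 2300 ± 98.2 CPM. The median of that list was 1.11 in C51 and 0.9 in WT cells of the same set. SQSTM1 changed by -0.19 ± 0.04 in C51 (adjusted p = 0.000258) and by -0.07 ± 0.04 in C64 (adjusted p = 0.115). Without C64 buffer replicate 1 SQSTM1 fell by 0.11 in C64 (edgeR quasi-likelihood test, adjusted p = 0.0302), and without C64 cGAMP replicate 1 by 0.13 (adjusted p = 0.00804). Cholesterol synthesis genes fell in 21 of 25 in C64, with 2 higher (median -0.996, adjusted p = 2.2e-07, and 0.012 with an estimated correlation). Hydrolases rose in 41 of 48 in C51, with 3 lower (median 0.50, adjusted p = 1.5e-08, and 0.016 with an estimated correlation), and in 32 in C64, with 5 lower (34 and 5 adjusted over the list alone; median 0.18, adjusted p = 0.00081, and adjusted p = 0.13 with an estimated correlation).

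Whether the cGAMP response depends on TFEB and TFE3 was tested as the mean response of C51 and C64 minus that of WT. The lines entered as fixed groups, so SE and p hold the spread between libraries and not that between lines. With only this pair of knockout lines, an effect of the genotype cannot be told apart from differences between lines. The response of SQSTM1 was lower in the knockouts by -1.04 ± 0.05 (adjusted p = 2.59e-15), that of FNIP2 by -1.40 ± 0.08, of FLCN by -0.56 ± 0.06, of RRAGC by -0.49 ± 0.06 and of GPNMB by -0.58 ± 0.05. GABARAPL1 went the other way (0.78 ± 0.04). Of 48 hydrolases and cofactors 32 responded less and 3 more (33 and 3 adjusted over the list alone; median -0.20, adjusted p = 7.6e-07, and 0.039 with an estimated correlation), with CTSS at -2.36 ± 0.12 and CTNS, the cystine exporter gene, at -1.30 ± 0.09. Of 29 membrane proteins 18 responded less (19 adjusted over the list alone; median -0.22, adjusted p = 5.2e-06, and 0.0066 with an estimated correlation), and of 19 V-ATPase subunits 13 did (median -0.20, adjusted p = 0.0012, and adjusted p = 0.062 with an estimated correlation). Autophagy genes were not called (12 more, 11 less; adjusted p = 0.56). Cholesterol synthesis genes responded less in 23 of 25 (median -0.93, adjusted p = 7.7e-19, and 0.00092 with an estimated correlation), for example HMGCS1 (-1.77 ± 0.06). Heat shock genes responded less in 10 of 16 and more in 1 (median -0.23, adjusted p = 0.006, and adjusted p = 0.18 with an estimated correlation). The test passed for 5959 of 15062 genes, 2667 with a higher response in the knockouts and 3292 with a lower one. The larger side was not stable: 44.8% were higher here, 50.7% with DESeq2 size factors and 50.9% with its Wald test. Without 1 library the share was 53% (WT cGAMP replicate 1 or 3, or C51 buffer replicate 3), 52.7% (C51 buffer replicate 1 or C64 cGAMP replicate 1), 52.8% (C51 buffer replicate 2) or 52.4% (C64 cGAMP replicate 3).

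The pair of lines differed for several of these groups, so each was also tested against WT. For cholesterol synthesis both responses were lower than in WT: 21 of 25 in C51 (median -0.59, adjusted p = 2.3e-13, and 0.0041 with an estimated correlation) and 23 in C64 (median -1.17; 1.1e-16, and 0.0016), or 22 and 24 adjusted over the list alone. SQSTM1 was lower by -1.10 ± 0.06 in C51 and -0.98 ± 0.06 in C64, and FNIP2 by -1.03 ± 0.10 and -1.77 ± 0.10. The hydrolases passed in C64 (37 of 48 lower, 1 higher; median -0.34, adjusted p = 1.7e-10, and 0.0087 with an estimated correlation) and not in C51 (20 lower, 5 higher; median -0.08, adjusted p = 0.2). Interferon-stimulated genes responded more than in WT in C51, 34 of 42 with 4 lower (35 and 4 adjusted over the list alone; median 0.69, adjusted p = 5.7e-17, and 0.0012 with an estimated correlation), and less in C64, 42 of 42 (median -3.11, adjusted p = 2e-39, and 1.6e-05). The mean of both lines therefore hides opposite signs for that list (37 of 42 lower, median -1.004, adjusted p = 1.3e-24, and 0.00019 with an estimated correlation). Mitosis genes responded more in C64 (24 of 24, median 1.40, adjusted p = 1.4e-23, and 0.0087) and were not called in C51 (3 higher, 2 lower; adjusted p = 0.53). Genes that passed numbered 5257 in C51 (2463 higher, 2794 lower) and 6968 in C64 (3157 higher, 3811 lower). In C51 the larger side turned, from 46.9% higher to 55.7% with DESeq2 size factors and 56% with its Wald test, and to 57.5% to 58.1% without WT cGAMP replicate 1 or 3 or C51 buffer replicate 1, 2 or 3. In C64 it was the lower side in every fit (45.1% to 49% higher). These contrasts share the WT libraries and are not independent of each other or of the WT comparison. In simulated data of the C51 contrast, with 200 genes and a smaller further list changed, 8.2% of 182 calls were false. Far more genes were called in the real contrast, so this share does not carry over to it.

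A smaller or larger response can come from a different start or a different end, so each line was set against WT in buffer and in cGAMP, in contrasts added after these results were seen. SQSTM1 in buffer was lower than in WT in C51 (-0.87 ± 0.04) and did not differ in C64 (0.01 ± 0.04, adjusted p = 0.8), and in cGAMP it was lower in both, by -1.97 ± 0.04 and -0.97 ± 0.04. FNIP2 in buffer did not differ in C51 (0.05 ± 0.07, adjusted p = 0.52) and was lower in C64 (-0.75 ± 0.07), and in cGAMP it was lower in both, by -0.98 ± 0.07 and -2.52 ± 0.07. The hydrolases started higher in C64, 34 of 48 with 8 lower (median 0.26, adjusted p = 6.7e-05, and adjusted p = 0.078 with an estimated correlation), and in cGAMP were not called against WT (18 higher, 19 lower; median -0.03, adjusted p = 0.96). In cGAMP they were not called in C51 either (18 higher, 21 lower; adjusted p = 0.9). Lysosomal membrane proteins in cGAMP were lower than in WT in 18 of 29 in C64, with 4 higher (median -0.30, adjusted p = 0.0035, and 0.043 with an estimated correlation), from a start not called (adjusted p = 0.71). In C51 they were lower in 19, with 4 higher (median -0.19, adjusted p = 0.011, and adjusted p = 0.098 with an estimated correlation), and in buffer in 15, with 8 higher (median -0.13, adjusted p = 0.046, and adjusted p = 0.14 with an estimated correlation). Genes of the RAG and folliculin branch in cGAMP were lower in 15 of 21 in C64, with 3 higher (median -0.26, adjusted p = 0.015, and 0.043 with an estimated correlation), from a start not called (adjusted p = 0.19). In C51 14 were lower and 4 higher (median -0.32, adjusted p = 0.015, and adjusted p = 0.072 with an estimated correlation), and in buffer 12 were lower and 1 higher (median -0.18, adjusted p = 0.018, and 0.044). V-ATPase subunits in cGAMP were not called in C51 (adjusted p = 0.61) or C64 (adjusted p = 0.7). Cholesterol synthesis genes started higher in C51, 20 of 25 with 2 lower (median 0.47, adjusted p = 5.6e-07, and 0.025 with an estimated correlation), and in cGAMP they were not called in C51 (median 0.05, adjusted p = 0.82). In C64 their start was not called (15 higher, 8 lower; adjusted p = 0.15), and in cGAMP 23 of 25 were lower than in WT (median -0.90, adjusted p = 1.5e-10, and 0.008 with an estimated correlation). Mitosis genes in C64 started at a median of -2.0 against WT and in cGAMP were still lower in 17 of 24, with 3 higher (median -0.35, adjusted p = 0.0015, and adjusted p = 0.4 with an estimated correlation). Interferon-stimulated genes in cGAMP were not called in C51 (adjusted p = 0.33) or C64 (adjusted p = 0.5). NF-kB targets lay on opposite sides of WT. In C64 27 of 30 were higher and 1 lower in buffer (median 1.19, adjusted p = 4e-10, and 0.015 with an estimated correlation). In cGAMP 26 were higher and 2 lower (median 1.49, adjusted p = 1.6e-10, and 0.0094). In C51 21 were lower and 4 higher in buffer (median -0.51, adjusted p = 1.6e-05, and 0.051 with an estimated correlation). In cGAMP 23 were lower and 4 higher (median -0.7, adjusted p = 8.2e-05, and 0.098).

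In buffer, the knockouts were compared with WT to see where the lines started. TFE3 (NCBI gene 7030, chromosome X, 49028726 to 49043357) was at 127 ± 2.36 CPM in WT, 36.7 ± 1.55 in C51 and 43.7 ± 1.1 in C64, and TFEB (NCBI gene 7942, chromosome 6, 41683978 to 41736223) at 9.62 ± 1.08, 5.17 ± 0.82 and 3.49 ± 0.35. FLCN and RRAGC were lower in the mean of both lines by -1.17 ± 0.04 and -0.58 ± 0.04, and PPARGC1A, a coactivator gene of mitochondrial biogenesis, by -3.02 ± 0.53. NRF2 targets were lower in the mean in 15 of 20 with 2 higher (median -0.45, adjusted p = 7.5e-05, and 0.04 with an estimated correlation). By line, 16 of 20 were lower and 2 higher in C51 (median -0.55, adjusted p = 2.3e-06, and 0.025 with an estimated correlation), and 12 lower and 3 higher in C64 (median -0.23, adjusted p = 0.032, and adjusted p = 0.2 with an estimated correlation). Mitosis genes were lower in the mean in 24 of 24 (median -1.11, adjusted p = 3.6e-16, and 0.04 with an estimated correlation). C64 made most of that fall, with 24 of 24 lower (median -2.0, adjusted p = 1.9e-17, and 0.028 with an estimated correlation), against 20 of 24 in C51 (median -0.27, adjusted p = 2.1e-05, and adjusted p = 0.23 with an estimated correlation). Interferon-stimulated genes were higher in 39 of 42 with 1 lower in the mean of both lines (median 0.96, adjusted p = 5.1e-18, and 0.00089 with an estimated correlation), but each line against WT gave 36 lower and 3 higher in C51 (median -0.81, adjusted p = 1.9e-12, and 0.0048 with an estimated correlation) and 42 higher in C64 (median 3.19, adjusted p = 9.5e-28, and 1e-04). In all, 9450 of 15062 genes passed, 4620 higher and 4830 lower.

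**Figure D2:**
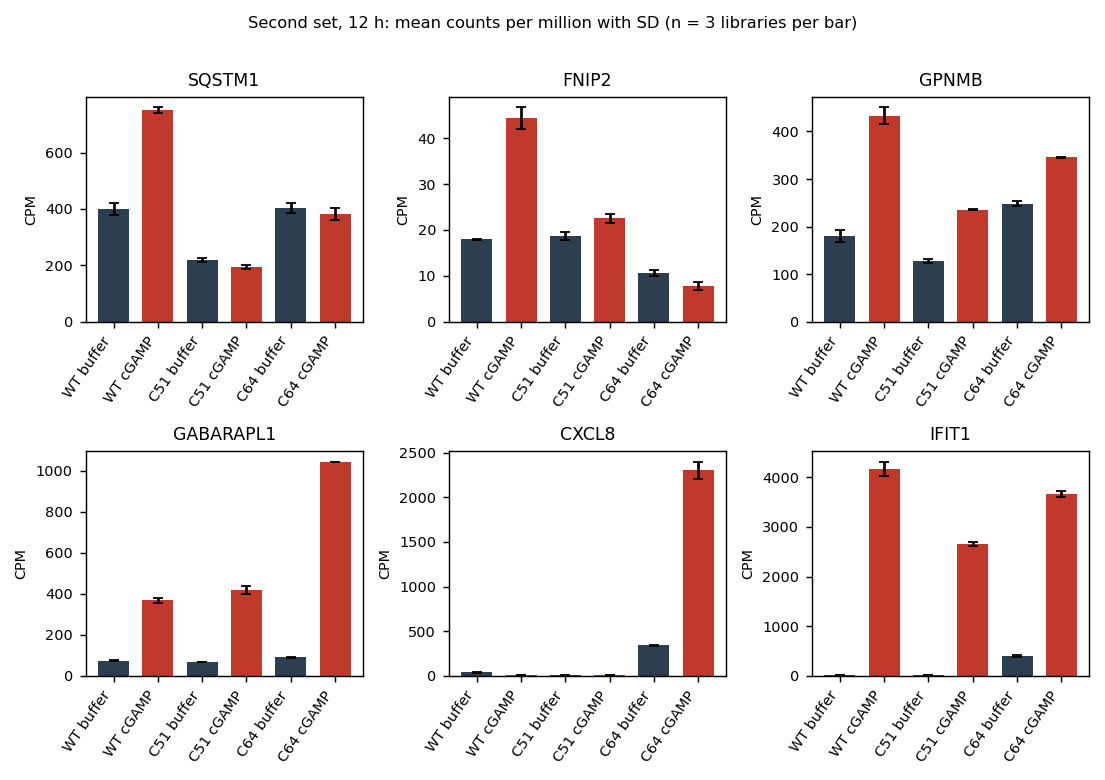
Mean CPM with SD (n = 3 libraries per bar) of 6 genes in the second BJ set at 12 h, in WT, C51 and C64 cells in buffer (dark blue) and in cGAMP (red), on linear axes from 0. SQSTM1 went from 400 to 751 CPM in WT, from 219 to 192 in C51 and from 403 to 383 in C64, while CXCL8 fell from 39.7 to 11.7 CPM in WT and rose from 344 to 2300 in C64. In C51 the log2 difference of CXCL8 from WT was -3.01 ± 0.09 in buffer and -0.63 ± 0.1 in cGAMP.

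Comparisons that share no library were set side by side. Of 8530 genes that passed at 12 h in WT cells of both BJ sets, 7511 (88.1%) had the same direction, with r = 0.792 and rho = 0.699 across 14450 genes. U2OS with DMXAA and BJ WT with cGAMP at 6 h had 7749 genes passing in both, 62.7% in the same direction, and r = 0.158 and rho = 0.219 across 13337 genes. The C51 and C64 responses had 9038 genes passing in both, 91.2% in the same direction. Genes are not independent replicates. With independent calls over the 14450 genes of the first pair, 3894.9 would pass in opposite directions, 2056.6 as higher in both and 1843.6 as lower in both, against 1019, 3941 and 3570 counted. Markers of other cell types gave no call in the comparisons planned before the data were examined: epithelial, endothelial and neural lists had adjusted p = 0.69, 0.14 and 0.32 in the second set's WT cells, and the blood cell list had 0.89 in the first set at 6 h. In the added contrast of the C64 and C51 responses the epithelial list was called, 5 of 7 lower and none higher (median -1.23, adjusted p = 0.036, and adjusted p = 0.077 with an estimated correlation).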

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

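The tests in this part were chosen after the results were seen, except the fits with 1 library left out and the differences WT minus STING knockout, 12 h minus 6 h, and C51, C64 or their mean minus WT. The C64 response minus that of C51 and the second set minus the first were also added after. The 3 patterns weighed were picked because they ran against what STING activation or the loss of TFEB and TFE3 would lead one to expect.

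Interferon-stimulated genes were already high in C64 cells in buffer. A candidate explanation is loss of TFEB and TFE3, but C51 in buffer had a median of -0.81 against WT, the other direction. RNA of cGAMP-treated C64 cells may have entered the buffer libraries: the shares of cGAMP level had a median of 18.8%, quartiles of 10.6% and 26.8% and a lowest value of 0.605%. The first test of this, the ratio of the upper to the lower quartile, gave 2.53, between the bounds set for it, so it decided nothing; the test used instead was chosen after that, and found 8 of 42 members below 50% of the median share in each library. A uniform mixture could then supply at most the lowest share, though a mixture at a low share beside other expression is not excluded.

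Mitosis genes rose at 12 h in WT cells of the first set and fell in the second. No single library of the first set made the rise, since the median was at least 0.90 with each of the 6 left out, and it was 1.03 after removing the trend with gene length. The responses differed between the sets by a median of -2.08 (24 of 24 lower; adjusted p = 2.3e-20, and adjusted p = 0.14 with an estimated correlation). In the second set the list's median with cGAMP was -1.12 in C51 and 0.46 in C64, so not all lines of that set had a fall. C64 started lower than WT in buffer (median -2), so its value does not settle the cause in WT cells. Kit, set and culture cannot be told apart here, and any of them might be the cause.

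Interferon-stimulated genes fell with DMXAA in U2OS cells, though the list's camera call was lost with an estimated correlation. Lower depth of the DMXAA libraries may lower weak genes, but with all libraries thinned to 10979492 reads the median was -0.94, with 20 of 26 members lower and 2 higher. After the trend with gene length it was -1.15. Of 10000 random lists matched on expression, 31 had as low a median, a share of 0.32% when the observed list is counted in. Those lists drew genes independently, so the share ignores correlation among interferon-stimulated genes. The pattern was also picked after its fall was seen, so the share is not a p-value. Random lists had a median of -0.41, so weakly expressed genes fell in general and part of the fall may be theirs.

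WT and STING knockout responses differed in 8252 genes at 6 h and 9283 at 12 h. The WT response at 12 h differed from that at 6 h in 8418 genes. The C51 response differed from WT in 5257 genes, that of C64 in 6968 and their mean in 5959. The C64 response differed from that of C51 in 7008 genes, with a median of -3.76 for interferon-stimulated genes. The WT response of the second set differed from that of the first in 6048 genes. WT cGAMP replicate 3 at 6 h had 15.9% of its reads on ribosomal RNA genes, and without those genes the WT count at 6 h was 9812 against 9831.

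Libraries were regrouped at random to ask whether such counts arise without the treatment. For 3 libraries against 3, 10 splits are too few for a share under 0.05: the real counts were 12114 in U2OS, 9831 and 10943 in WT at 6 h and 12 h, 0 and 0 in STING knockout cells, 4455 and 5242 for knockout against WT in buffer, 10681 in the second set's WT, 11184 in C51 and 10786 in C64. The highest count of the other splits was 1 in WT at 6 h and 0 in each of the rest, and in STING knockout cells 10 of 10 splits gave as many genes. For the differences between responses 1 of 80 splits, the real one, gave as many genes, and the highest other count was 0, or 1 for 12 h minus 6 h. These 80 were limited to splits that mix each arm, a limit set after splits that kept an arm whole and reversed its treatment had given many genes: 8140 and 9586 for WT minus knockout at 6 h and 12 h, 11369 for 12 h minus 6 h, 11861 for C51, 11649 for C64 and 9586 for the mean of both. Such a reversal adds the 2 responses instead of subtracting them, and a split that mixes treated and control libraries raises the spread within groups, which keeps its count low. Neither kind shows what chance alone would give, so these splits do not decide whether chance can be excluded for the differences between responses. For C51 and C64 against WT in buffer 1 of 84 splits gave as many genes as the 9450 counted. The median of the other splits was 0. Mixing lines within a group raises the spread there and keeps a count low, so this share does not decide whether chance can be excluded. The highest other count, 8211, came from the split of the 3 C64 buffer libraries against the other 6, and points to a structure of the samples.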

How the results depend on the processing

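Alternatives chosen after the data were seen are the fits without ribosomal RNA genes and the thinned U2OS libraries. No called value of a named gene reversed direction in the settings run. The list tests were rerun only with an estimated correlation and with a replicate block. The first cannot turn a direction and in the second the direction was not compared, so whether list calls reverse was not tested. In STING knockout cells, where edgeR gave 0 genes, DESeq2's Wald test gave 1 gene at 6 h and 17 at 12 h, and a fit of only the groups compared gave 23 at 12 h. Counts over the other settings, and with 1 library left out, were 11154 to 12531 and 11569 to 11914 in U2OS, 9702 to 9870 and 9218 to 9499 in WT at 6 h, 9586 to 11066 and 10489 to 11128 in WT at 12 h, 10364 to 10822 and 10242 to 10395 in the second set's WT, and 5870 to 5962 and 5389 to 6038 for the mean of C51 and C64 minus WT. Of the named genes, 161 values were weaker, 38 stronger and 11606 the same with 1 library left out, and 40, 37 and 10587 in the other settings. With an estimated correlation 121 list results lost their call and 312 were the same. With the replicate number as a block 1 was lost and 1 gained. For genes and lists, values counted as the same include those called in neither fit, so they do not count calls that held. Of genes called in C51 minus WT, 46.9% were higher, and 57.5% to 58.1% without WT cGAMP replicate 1 or 3 or any of the 3 C51 buffer libraries. The larger side also turned in some fits of U2OS, WT at 6 h, the second set's WT, C51 and C64 against their own controls, with shares between 47% and 52.6%. It turned as well for WT minus STING knockout, with 48.5% to 50.2% higher at 6 h and 48.8% to 51.2% at 12 h. For the mean of C51 and C64 minus WT the share higher was 44.6% to 53%. The largest shift of the median of all genes under a setting was 0.05.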

Other observations

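The tests in this part are those of the report, and the reading of these genes side by side was made after the results were seen.

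STING1 itself responded to cGAMP in the second set, from 92.5 ± 1.55 to 529 ± 3.83 CPM in WT, from 91.1 ± 2.21 to 644 ± 1.25 in C51 and from 175 ± 4.82 to 421 ± 8.97 in C64 cells (n = 3 each). GABARAPL1, an ATG8-family gene of autophagy, rose in all 3 of these lines, from 74.3 ± 2.54 to 368 ± 10.5 CPM in WT, from 66.9 ± 0.82 to 419 ± 17.6 in C51 and from 90.6 ± 2.24 to 1043 ± 1.31 in C64. FNIP2, a partner of folliculin, rose in WT (1.31 ± 0.07) and C51 (0.28 ± 0.07) and fell in C64 (-0.46 ± 0.08). AJAP1, with no read in STING knockout buffer libraries, was also near absent in C51 buffer libraries (0.0366 ± 0.035 CPM) and at 60.8 ± 0.88 CPM in C64.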
